A study of Mus musculus with 9 samples.

How the data were processed

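Gene expression was measured in hematopoietic stem cells (HSCs) sorted from the bone marrow of mice aged 6 to 8 months. Per the labels' protocols, mice with a floxed Bcl11a gene were crossed to Mx1-Cre mice, in which interferon switches on the Cre recombinase, and received 5 doses of poly(I:C), a synthetic RNA that induces interferon. The 3 genotypes were wild-type (WT, both alleles floxed, no Cre), heterozygous (Het, 1 floxed allele, Cre) and knockout (KO, both alleles floxed, Cre), with 3 biological replicates each and 1 array per replicate. The WT group therefore differs from the other groups in Cre as well as in Bcl11a. The gate was negative for lineage markers, CD48 and Flt3 and positive for Sca-1, Kit and CD150, with cells taken as YFP-positive or YFP-negative; which of these applied to which array is not given in the sources used here. RNA was amplified with a single-primer isothermal method for small inputs, labelled with biotin and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. Strong amplification of RNA from few cells can add spread between arrays.

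The deposited values were log2 summaries per probe set, made by the authors with RMA, per the submitters' processing notes; its version and settings, and a genome build, are not given in the sources used here, so no coordinates are printed. RMA estimates and removes background, normalizes arrays to each other and combines the probes of a set, which compresses differences of dim transcripts. Medians of the 9 arrays lay between 3.95 and 4.15 and interquartile ranges between 2.22 and 2.83 on the log2 scale. No detection p-values were used. Sex-linked transcripts gave a scale for absent transcripts: the Y-linked genes read 2.22 to 3.32 on the 4 arrays with high Xist, and Xist read 3.58 to 4.22 on the other 5 arrays. On those 5 arrays the Y-linked genes read 3.86 to 8, so a dim transcript that is present can fall in this range too. The number of arrays, not a count depth, limits the precision; the median standard error of the KO minus WT difference was 0.298.

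Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 were not listed there. Symbols were updated through gene identifiers, which matched for 23328 probe sets and not for 193. Each of 22180 genes was represented by its probe set with the highest mean over the 9 arrays; 1082 genes had several. Genes with a mean under the 25th percentile, at a log2 value of 3.31, were left out of the tests, which removed 5544 genes and kept 16636. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean per genotype over all 9 arrays, so that the groups shared an estimate of the spread with 6 residual and 4.26 prior degrees of freedom. The comparisons were KO with WT, Het with WT and KO with Het, plus a linear term in the number of deleted alleles. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, and genes were called at an adjusted p under 0.05.

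Before the data were examined, 23 gene lists were fixed from textbook knowledge: stem cell, lineage, cell cycle, interferon, apoptosis, respiration, ribosome and chromatin genes, immediate early genes, markers of other cell types that a bone marrow sort could hold, and sex-linked genes, which were not tested. A list was tested if it had at least 3 tested members, which left 21 lists; the embryonic globin genes all lay under the level of the filter. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which assumes nearly independent genes, and again with the correlation estimated from the data and with fry. Members were also adjusted over the list alone.

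The genes named were set by a rule fixed in advance: Bcl11a; up to 12 genes in each direction with the largest fold among those called; where fewer than 5 passed, the 8 with the smallest p in that direction, leaving out predicted genes, small RNAs and olfactory or vomeronasal receptors; up to 4 members per list; and always Cdk6, Ccnd1, Cdkn1c, Flt3, Il7r, Vwf, Selp and Slamf1. Gene symbols chosen outside this rule are said to be so.

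The fit was tested on simulated data with the spread of these arrays and 200 changed genes among 16636. For KO with WT, it recovered 15.4% of genes changed by a log2 size of 1, 64.6% at a size of 2, 71.6% at 3 and 78.6% at 4, with a mean of 5.4 false calls per simulation. Changed genes that fell under the filter counted as not recovered. The Benjamini-Hochberg cut is looser when many genes change. These shares therefore overstate the recovery to be had in the real comparison, in which 7 genes were called. Recovery with fewer changed genes was not simulated. A list shifted by 0.5 was called in 10 of 10 simulations. The simulated genes were drawn independently, so this does not test the list calls for correlated genes. On the real arrays the HSC identity list had an estimated correlation of 0.329.

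Alternatives fixed in advance changed the filter, the normalization, the probe set per gene, the variance model, array weights, the arrays in the fit, the threshold, the list test, the replicate number as a block, and left out each replicate in turn. A term for the sex of the animals, read from Xist and Y-linked transcripts, a term for the interquartile range of each array, and a fit without both WT replicate 1 and KO replicate 3 were chosen after seeing the data. Correlations of the Het and KO changes were set against 100 simulations of unchanged groups that share the WT arrays. A division of the WT arrays between the comparisons, with its own 100 simulations, was added after seeing the data. Drawings were made with Python 3.11.15.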

Results

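Sorted HSCs were profiled on 9 arrays, 3 each from WT, Het and KO mice, to ask what loss of 1 or both copies of Bcl11a does to the expression programme of stem cells. Bcl11a encodes a zinc finger repressor known for silencing fetal globin and for its need in lymphoid development. Values are log2 expression, given as mean ± SD with n = 3 arrays per genotype, and the labels call the replicates biological. Arrays of the same genotype correlated with Pearson's r of 0.862 to 0.932 across probe sets. Xist and Y-linked transcripts showed that the sexes were not balanced: 2 of 3 WT arrays, 1 of 3 Het arrays and 1 of 3 KO arrays came from female mice.

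Bcl11a itself read 8.64 ± 0.229 in WT, 8.53 ± 0.309 in Het and 8.13 ± 0.464 in KO cells. Neither difference from WT passed the test (KO minus WT −0.51, SE 0.288, adjusted p = 0.655; Het minus WT −0.11, adjusted p = 0.993), and the exact two-sided permutation p was 0.2 for KO and 0.8 for Het, where 0.1 is the smallest that 3 arrays against 3 allow. The KO arrays did not read alike: replicates 1 and 2 read 7.82 and 7.90, below every WT and Het array, while the array labelled KO replicate 3 read 8.66, inside the WT range of 8.38 to 8.81. Without it the difference was −0.78. A second Bcl11a probe set gave a difference of 0.07. The part of the gene removed and the positions of the probes are not given in the sources used here, so these values cannot show whether the deletion took place. Within female mice KO minus WT was 0.11 (1 KO and 2 WT arrays) and within male mice −0.95 (2 and 1). Every KO average below includes the array labelled KO replicate 3.

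**Figure D1:**
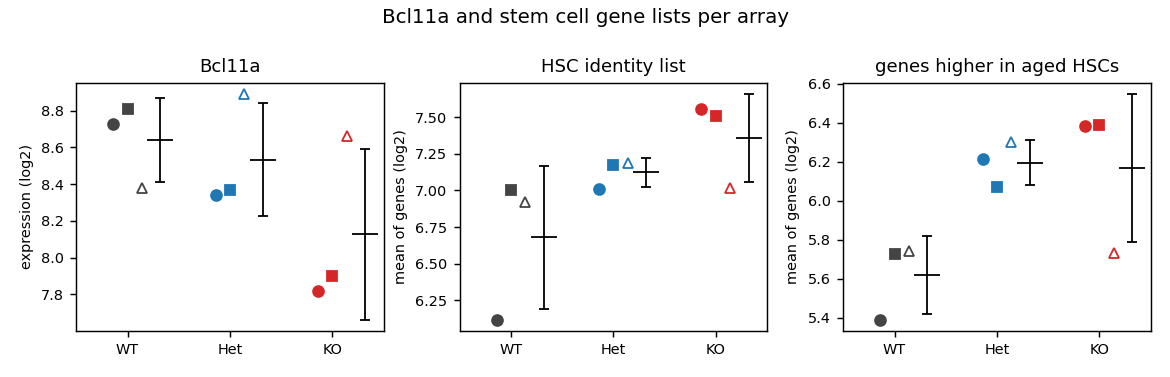
Log2 expression of Bcl11a and the mean log2 expression of the tested members of the HSC identity list and of the list of genes higher in aged HSCs, on each of the 9 arrays (circle, square and open triangle for replicates 1, 2 and 3; black line and bar for the mean ± SD of 3 arrays). The array labelled KO replicate 3 read 8.66 for Bcl11a, 7.01 for the HSC identity list and 5.73 for the aged list, apart from the other KO arrays.

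The comparison of KO with WT asks what complete deletion changes. In KO cells, 6 genes rose and 1 fell among 16636 tested (adjusted p under 0.05). Tyrobp, a signalling adaptor of immune receptors on myeloid and NK cells, rose from 5.64 ± 0.0289 to 8.89 ± 0.895, which is 9.47-fold (log2 difference 3.24, SE 0.426, adjusted p = 0.0432). Cysltr2, a receptor for cysteinyl leukotrienes, rose 8.84-fold (3.14, SE 0.365, adjusted p = 0.0289). Aoah, a lipase that inactivates bacterial lipopolysaccharide, rose 8.22-fold and Sox18, a transcription factor of endothelial development, 7.59-fold. F10, the gene of coagulation factor X, rose 3.89-fold, from 4.03 ± 0.290 to 5.99 ± 0.401. The predicted gene Gm17745, named here after its values were seen, rose by 4.57 with an adjusted p of 0.0282. WT levels of Aoah (2.89), Gm17745 (3.61), Sox18 (3.79) and F10 (4.03) lay in the range in which absent transcripts read. Their folds and differences may therefore start from background. Ctla2a, an inhibitor of cysteine proteases, was the gene that fell, from 10.09 ± 0.133 to 8.28 ± 0.171 (−1.81, SE 0.231, adjusted p = 0.0432). Within female and within male mice Tyrobp differed by 4.15 and 2.78 and Ctla2a by −1.88 and −1.84.

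The genes with the next smallest p among those lower in KO did not pass the threshold. They were Pdzd11 (−1.13), Mrgpra2a (−1.41), Plxdc2 (−2.04), Vim, the intermediate filament vimentin (−1.28), Gpr65, a proton-sensing receptor (−1.27), Cdk6 (−1.03) and Aldh1a1, a retinaldehyde dehydrogenase (−1.18), with adjusted p from 0.175 to 0.259; Mrgpra2a read in the range of absent transcripts in KO cells. At an unadjusted p under 0.05, 1366 genes differed, 899 higher and 467 lower, where chance gives 832. The count of 7 depended on single arrays: it was 0 without WT replicate 1 or KO replicate 1, 1 without WT replicate 2 or Het replicate 1, 2 without WT replicate 3 or KO replicate 2, 3 without Het replicate 3 and 15 without KO replicate 3. With sex as a term 3 genes were called, with the interquartile range of the arrays as a term 0, and after a further quantile normalization 3, of which 3 rose and 0 fell. Over all 41345 probe sets without a filter none of the 7 genes was called, with adjusted p from 0.0512 to 0.126.

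**Figure D2:**
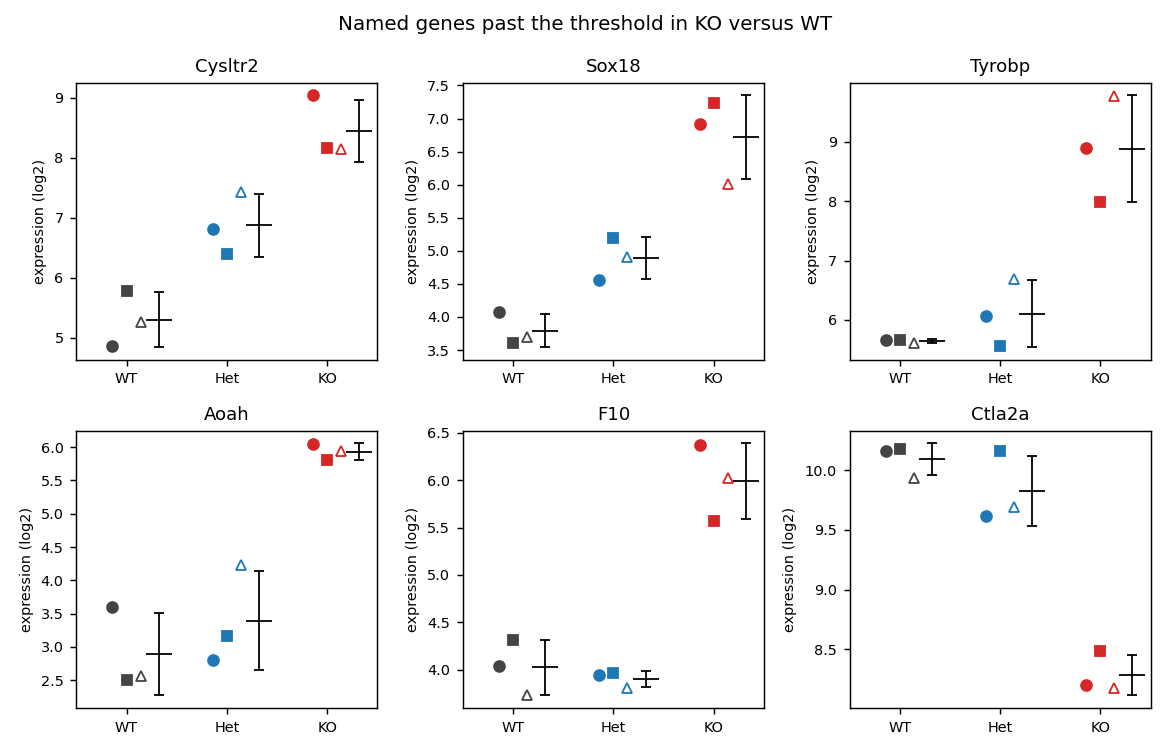
Log2 expression on each array of the 6 genes past the threshold in KO versus WT that the naming rule covers (circle, square and open triangle for replicates 1, 2 and 3; black line and bar for the mean ± SD of 3 arrays). Cysltr2 and Sox18 read higher on every Het array than on any WT array and higher still on every KO array, while F10 read 3.90 in Het and 4.03 in WT cells.

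Genes that mark or maintain HSCs were higher in KO cells as a group: 29 of 33 tested members were higher, with a median log2 difference of 0.56 (camera adjusted p = 1.18e-08). The call was lost with an estimated correlation (adjusted p = 0.548, at a correlation of 0.329). No member passed over all genes, and 4 rose adjusted over the list alone: Hoxb5, a marker of long-term stem cells, from 5.26 ± 0.347 to 7.49 ± 0.361; Mecom, a transcription factor that stem cells need, by 1.94; Mllt3, a chromatin reader that maintains them, from 8.05 ± 0.118 to 9.59 ± 0.228; and Fgd5, a stem cell marker, by 1.24. The mean of the list was 7.36 ± 0.298 in KO and 6.68 ± 0.488 in WT cells, with an exact permutation p of 0.1, the smallest possible. The difference of list means was 0.50 within female mice (1 KO array at 7.01, 2 WT arrays at 6.12 and 6.92). Within male mice it was 0.52 (2 KO arrays, 1 WT array). The female value thus rests largely on the low reading of WT replicate 1. On the same arrays the mean over 7 lists of other cell types differed by −0.18. The median of the HSC list shrank more than 1.5 times without WT replicate 1 (0.31) and with the interquartile range as a term (0.35), with the camera call kept in both.

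Genes known from other studies to be higher in HSCs of old mice were also higher in KO cells. Of 38 tested members 29 were higher, with a median difference of 0.46 (camera adjusted p = 1.70e-04; adjusted p = 0.548 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. Neo1, the netrin receptor neogenin, differed by 2.46, Jam2, a junctional adhesion molecule, by 1.89, Vwf, the von Willebrand factor, by 1.55, Selp, P-selectin, by 1.52 and Mllt3 by 1.53; Clca3a1 was the other riser and Aldh1a1 the member that fell. Slamf1, the gene of the gate marker CD150, read 5.34 ± 1.19 in WT, 7.09 ± 0.416 in Het and 6.97 ± 0.844 in KO cells (KO minus WT adjusted p = 0.543). On the array labelled KO replicate 3 the list mean was 5.73, where the WT arrays read 5.39, 5.73 and 5.74 and the other KO arrays 6.38 and 6.39. The KO minus WT difference of the list mean was 0.16 within female and 0.66 within male mice (exact permutation p over all mice 0.2).

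Lineage and progenitor genes did not pass as lists. Markers of multipotent progenitors, which the gate excludes, were lower for 9 of 10 members (median −0.27, adjusted p = 0.274). Flt3, an early lymphoid and progenitor receptor, read 4.78 ± 0.709 in WT and 3.72 ± 0.272 in KO cells and, with Cd52, fell adjusted over the list alone, while Cd34, a surface marker low on mouse HSCs, rose in that test, from 7.94 ± 0.14 to 9.56 ± 0.507. The WT and KO arrays of Flt3 overlapped. Its KO minus WT difference was −1.6 within female mice (1 KO and 2 WT arrays) and −0.2 within male mice (2 and 1). Lymphoid priming genes had a median difference of −0.19 with 19 of 26 members lower (adjusted p = 0.436); Il7r, the interleukin receptor of lymphoid progenitors, lay under the filter at 2.59 ± 0.342 in WT and 2.85 ± 0.680 in KO cells. Granulocyte and monocyte genes were lower for 18 of 26 members (median −0.20, adjusted p = 0.133), among them S100a8, a neutrophil calcium-binding protein, at 8.66 ± 0.282 in WT and 4.80 ± 2.26 in KO cells, and Lyz2, lysozyme, at 9.29 ± 0.145 and 8.26 ± 0.623. Members went both ways: Cd68 and Itgam, named after their values were seen, were higher in KO cells by 1.63 (adjusted p = 0.557) and 1.21 (0.563), Itgam from a WT level in the range of absent transcripts. Megakaryocyte and platelet genes split evenly (median −0.01, mean 0.10), with F2rl2 at −1.18, and erythroid genes had a median of −0.17, with Epor at 0.70 and Tspo2 at −0.83. Flt3 and Tspo2 read in the range of absent transcripts in KO cells. The 4 embryonic globin genes, Bcl11a targets in red cells, lay under the filter: on all arrays Hbb-y read 2.12 to 2.88, Hbb-bh1 2.01 to 2.71, Hbb-bh2 2.87 to 3.94 and Hba-x 2.39 to 4.94.

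Among cell cycle regulators, Cdk6, the kinase that drives exit from quiescence, read 9.01 ± 0.306 in WT, 8.32 ± 0.00577 in Het and 7.98 ± 0.0808 in KO cells; it fell adjusted over its list alone but not over all genes (adjusted p = 0.237). Ccnd1, the cyclin D partner, read 6.35 ± 0.553 in WT and 6.51 ± 0.141 in KO cells, Cdkn1c, a cell cycle inhibitor of quiescent HSCs, 4.61 ± 0.189 and 4.70 ± 0.146, and Btg1 differed by −0.69. The list's median was 0.07 and its mean −0.02. Proliferation genes had a median of −0.08 (Aurkb −0.73, Gins1 0.97), interferon-stimulated genes 0.23 (adjusted p = 0.0833; Irf9 0.68, Gbp7 1.10), apoptosis and p53 genes −0.15 (Bcl2 −0.80, Mdm4 0.85), respiratory chain genes −0.08 (Cox7a2 −0.75, Ndufs4 0.97), ribosomal protein genes 0.01 (Rplp2 −0.77, in the range of absent transcripts in KO cells, and Rps27 0.63) and chromatin complexes that bind BCL11A 0.13 (Smarcc2 0.64, Smarcd2 −0.57). Immediate early and stress genes had a median of 0.19 (adjusted p = 0.0833); Jund rose adjusted over the list alone, from 6.68 ± 0.0252 to 8.54 ± 0.760, and Fosb differed by 1.84.

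Markers of other blood and marrow cells were lower on most counts. Median differences were −0.27 for B cells (11 of 12 members lower; H2-Ab1 −1.38), −0.26 for T and NK cells, −0.33 for mast cells and basophils (Il13 −0.46), −0.21 for plasmacytoid dendritic cells (Siglech −0.47, Ly6d −0.43), −0.09 for macrophages (Mertk 0.88, Spic 0.99) and −0.15 for stroma and endothelium, whose mean was 0.02 (Kdr 1.24, Emcn 1.19). None of these lists passed, with adjusted p from 0.133 to 0.692. Cd79a, at 3.68 in WT and 3.22 in KO cells, and Cpa3, at 3.95 and 3.09, read in the range of absent transcripts in both groups, as did Il13 and Siglech in KO cells and Mertk, Spic and Kdr in WT cells. Within the T and NK list, adjusted over the list alone, Klrb1c, an NK cell receptor, rose from 4.23 ± 0.629 to 6.42 ± 0.568 and Nkg7, a cytotoxic granule protein, fell from 6.67 ± 1.05 to 4.91 ± 0.146.

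The comparison of Het with WT asks what loss of 1 allele does. No gene passed with limma (smallest adjusted p = 0.559); at an unadjusted p under 0.05, 813 genes differed, 519 higher and 294 lower, where chance gives 832. The higher genes with the smallest p were Myl6b (1.92), Iqcc (1.55), Trappc3 (2.12), B4galt6 (2.11), Obi1 (1.59), Vps72 (1.18), Sec31a, a coat protein of vesicle transport (1.02), and St7 (1.01). The lower ones were Pdzd11 (−1.40), Slc16a9 (−1.94), Acadm, an enzyme of fatty acid oxidation (−1.26), Ndufaf7 (−1.31), Cd69, an early activation marker (−1.99), Unc93a (−1.06), Eloc (−1.24) and Mto1 (−0.94). Myl6b and Iqcc in WT cells, and Slc16a9, Cd69 and Unc93a in Het cells, read in the range of absent transcripts.

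Of the 21 lists, 4 passed at the preset correlation. Genes higher in aged HSCs were higher in Het cells for 30 of 38 members (median 0.47, camera adjusted p = 2.67e-07; adjusted p = 0.212 with an estimated correlation). Adjusted over the list alone 9 rose, among them Alcam (1.12), Jam2 (1.14), Selp (1.33) and Slamf1 (1.75), and 1 fell, Gpr183, a receptor that guides lymphocytes (−1.19). The list mean was 6.20 ± 0.117 in Het and 5.62 ± 0.198 in WT cells, with no overlap of the arrays (exact permutation p = 0.1, the smallest possible), and the difference was 0.74 within female and 0.42 within male mice. HSC identity genes were higher for 28 of 33 members (median 0.50, adjusted p = 4.16e-06; adjusted p = 0.861 with an estimated correlation), with Mllt3 at 9.05 ± 0.211 against 8.05 ± 0.118 in WT, Mecom higher by 1.29 and Erg by 0.84, but without WT replicate 1 the median was 0.17 and the call was lost (adjusted p = 0.103), as it was without both WT 1 and KO 3. The median also shrank more than 1.5 times, with the call kept, with sex as a term (0.236, under 50% of its size), with array weights (0.287), with the interquartile range as a term (0.314) and without Het replicate 3 (0.317). The difference of its list means was 0.67 within female and 0.09 within male mice.

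Immediate early and stress genes, which respond to handling of cells, were higher in Het cells (median 0.31, adjusted p = 0.0219; adjusted p = 0.861 with an estimated correlation), with Jun at 1.81, Jund at 1.30, Fosb at 1.78 and the heat shock gene Hspa1b at 3.80. Apoptosis and p53 genes were lower for 16 of 21 members (median −0.24, adjusted p = 0.0221; adjusted p = 0.212 with an estimated correlation), with the survival factor Bcl2 at −0.80, Mdm2 at −0.59 and Casp9 at −0.38. Both calls were lost when any of 4 arrays was left out. Without WT replicate 1, WT replicate 3 or Het replicate 2 the stress median was 0.255, 0.415 and 0.337 (adjusted p = 0.103, 0.208 and 0.0613), and without Het replicate 1 it shrank more than 1.5 times, to 0.182 (0.304). For the apoptosis list the median was −0.175, −0.228 and −0.273 without WT replicate 1, WT replicate 3 or Het replicate 1 (adjusted p = 0.109, 0.109 and 0.0825), and without Het replicate 2 it shrank more than 1.5 times, to −0.157 (0.139). With sex as a term the stress median was 0.154 (0.0834), under 50% of its size, while the apoptosis median kept its size at −0.245 (0.0622). The stress call was also lost when quantile normalized again (0.346, adjusted p = 0.0631) and with the interquartile range as a term (0.209, 0.0590), and the apoptosis call without a filter (−0.202, 0.259). The stress median grew more than 1.5 times, with the call kept, among genes at or above the median level (0.550) and without WT replicate 2 (0.480). Among the genes always given, Cdk6 differed by −0.69, Flt3 by −0.79 with its Het level in the range of absent transcripts, Vwf by 0.72, Ccnd1 by −0.54 and Cdkn1c by 0.20. None of these passed over all genes.

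The direct comparison of KO with Het tests whether the second allele matters. No gene passed with limma; Gatm, an enzyme of creatine synthesis, and F10 came closest, at 2.08 each and an adjusted p of 0.0881. At an unadjusted p under 0.05, 759 genes differed, where chance gives 832. Higher in KO than in Het cells were also Tyrobp (2.78), Aoah (2.53), Hk3, a hexokinase of myeloid cells (1.53), Sox18 (1.83), Ackr1 (1.66) and Hoxb5 (1.70). Lower were Ctla2a (−1.54), Ccdc117 (−1.44), St7 (−1.15), Myl6b (−1.38), Cox18 (−1.40), Ublcp1 (−0.92) and Iqcc (−1.10), and Plagl2 read 6.98 ± 0.0436 in Het and 5.98 ± 0.0551 in KO cells, none past the threshold. F10, Aoah and Ackr1 in Het cells, and Ublcp1 and Iqcc in KO cells, read in the range of absent transcripts. Of the 21 lists none passed; the HSC identity list came closest (median 0.12, adjusted p = 0.0710), and the aged list had a median of −0.09 (adjusted p = 0.920). Hoxb5 rose within the HSC list alone, Cd34 within the progenitor list alone and Klrb1c within the T and NK list alone.

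Across the allele series, 3 genes rose with the number of deleted alleles. Cysltr2 rose by 1.57 per allele (SE 0.174, adjusted p = 0.0152) and Sox18 by 1.46 (SE 0.169, adjusted p = 0.0160), both with Het cells in between, at 6.88 ± 0.523 and 4.89 ± 0.316. Gm17745, outside the naming rule, rose by 2.29 per allele (SE 0.228, adjusted p = 0.0111). WT levels of Sox18 and Gm17745 lay in the range of absent transcripts. Over all probe sets without a filter 0 were called with limma. Without KO replicate 1 or KO replicate 2 none was called, without Het replicate 2 there were 6 and without KO replicate 3 there were 14; with sex as a term 1 was called and with the interquartile range as a term 0.

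Changes of Het and KO cells from WT correlated across the 16636 genes (r = 0.609, Spearman's rho 0.575), and 71.1% had the same sign; genes are not independent replicates. Both comparisons use the same WT arrays, which alone gave a simulated r of 0.50 and the same sign for 66.7% of genes. The covariance was 0.116, against 0.0788 in the simulation. WT arrays were then divided so that none was shared, 1 going to one comparison and the other 2 to the other. Over the 6 divisions r was −0.0452 to 0.167, with a mean of 0.0878. Most of the correlation thus came from the shared WT arrays. Simulated unchanged groups gave means of −0.0243 to 0.0304. Their genes were drawn independently, so this range cannot tell whether 0.0878 exceeds chance for correlated genes. Of the 7 genes called in KO cells, 6 had the same sign in Het cells, with a mean Het change of 24.5% of the KO change, where the simulation of unchanged groups gave 49.9%.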

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

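All tests of explanations in this part were chosen after the results were seen; the counts over other splits of the arrays were planned. When all probe sets were tested, named or not, 7 were called in KO versus WT and 6 in Het versus WT, and none of these has a single gene symbol in the annotation, so they enter no comparison of genes. The 6 of the Het comparison were among the 7 of the KO comparison, and 3 of them held identical values on all 9 arrays. On each, all Het and KO arrays lay outside the WT range. Probe set 17549072 read 6.87 ± 0.329 in WT, 10.29 ± 0.293 in Het and 9.87 ± 0.141 in KO cells (n = 3 each), and probe set 17549150 went the other way, from 6.95 ± 0.165 to 4.24 ± 0.166 and 4.26 ± 0.381. The 6 thus separated mice without Cre from mice with Cre, and on 1 of them all Het arrays also lay above all KO arrays, which chance gives on one side or the other for 10%. The remaining 1, probe set 17207339, was called in KO versus WT and not in Het versus WT. It read 1.26 ± 0.18 in WT, 2.24 ± 0.396 in Het and 4.29 ± 0.318 in KO cells, with the 3 groups apart. All its WT and Het arrays, and KO replicates 1 and 2 at 4.02 and 4.21, read no higher than absent transcripts do, up to 4.22.

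The wild-type reading of Bcl11a on the array labelled KO replicate 3 was set against wrong labels, with 2 tests run for each label and all 4 given here. On the 6 probe sets above this array stood at 84.3% from the WT mean at 0% to the Het mean at 100%. The WT arrays stood at −12.0% to 13.4%. These probe sets hold 4 distinct profiles and were called in a fit whose spread included this array. A probe set on which it read apart from the other KO arrays was thus less likely to be called. For this reason the test cannot exclude a wild-type sample under a KO label. An earlier test on the 100 genes that best part the other KO arrays from WT decided nothing. It gave 56.3%, against 12.8% to 44.1% for held-out WT arrays (SD 16.9). Held-out KO replicates 1 and 2 stood at 83.9% and 63.4%. KO replicate 3 helped to pick their genes and set their scale, so they are no like reference. A Het sample under a KO label cannot be told apart from a KO sample, as the tests differ. On the 15 genes called without this array it stood at 55.9% of the way from WT to the other KO arrays. That lay above the Het arrays at 38.9% to 52.6% by less than their SD of 6.88. An earlier test used the 100 genes that best part those KO arrays from Het. There it stood at 40.8%, inside the held-out Het range of 21.7% to 56.8%. Held-out KO replicates 1 and 2 stood at 57.4% and 50.3%. Their genes and scale again depended on KO replicate 3, so they are no like reference. Single genes went both ways: this array lay above all Het arrays in 5 of the 15 genes, as for Tyrobp at 9.78, and below or among them in the others, as for Dok5 at 3.51, while F10 at 6.02 (Het 3.81 to 3.96), Aoah at 5.94 (2.80 to 4.23), Ctla2a at 8.17 (9.62 to 10.16) and probe set 17207339 at 4.64 (1.96 to 2.69) read as on the other KO arrays, all 4 called with this array in the fit, with KO minus WT at 1.94, 3.04 and −1.75 without it for the 3 genes. Incomplete deletion in this mouse and probes outside the deleted part stay open and were not tested.

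The higher level of HSC identity genes in KO cells was 0.68 as a difference of list means (95% interval 0.00772 to 1.35). With the interquartile range of the arrays as a term it was 0.42 (−0.14 to 0.97), and with sex as a term 0.58 (−0.11 to 1.26); both intervals hold 0 and the differences stayed above 50% of the first value, so neither array spread nor sex can be told apart from genotype. Within female mice the difference was 0.50 (1 KO array, 2 WT arrays) and within male mice 0.52 (2 and 1). Fewer other cells in the KO sorts could raise stem cell genes: the mean over 7 lists of other cell types differed by −0.18 (−0.33 to −0.017), but stroma and endothelium was not lower (0.02, −0.19 to 0.24), which leaves this open too. A larger share of stem cells in the gate and a change within them also stay open.

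Tyrobp and Aoah, genes of myeloid and NK cells, were higher in KO cells by 3.24 (95% interval 2.02 to 4.47) and 3.04 (1.92 to 4.16), and other cells in the sort were weighed with 6 abundant transcripts each of 3 cell types. Cells of these types would bring their abundant transcripts with them, but neutrophil and monocyte transcripts (S100a8, S100a9, Lyz2, Ngp, Camp and Ltf) had a mean difference of −1.41 (upper bound 0.04), NK cell transcripts (Nkg7, Ccl5, Gzma, Klrb1c, Prf1 and Ncr1) −0.0878 (upper bound 0.14) and macrophage transcripts (C1qa, C1qb, C1qc, Cd5l, Vcam1 and Hmox1) −0.42 (upper bound 0.29). These bounds lie below the lower bounds of Tyrobp and Aoah, so no set as a whole rose as those genes did. Not every marker could rise that far. Camp, Gzma, Ncr1, Cd5l and Vcam1 read in the range of absent transcripts in both groups, where differences are compressed. S100a8 and Lyz2 were already high in WT cells, so added cells would raise them less. The means therefore cannot exclude the 3 cell types as the source. Each mean pools transcripts, so a rise in 1 kind of cell within a set could be hidden by a fall in another. Klrb1c alone among the NK transcripts was higher, at 2.18 (1.01 to 3.36), while Nkg7 was lower, at −1.75. Higher as well were 3 other genes of myeloid cells, named after their values were seen: Fcer1g at 1.80 (1.20 to 2.41), Cd68 at 1.63 and Itgam at 1.21. The lineage gate does not settle the question, as S100a8 read 8.66 and Lyz2 9.29 in WT cells. Array spread was weighed with the interquartile range as a term. Tyrobp then differed by 3.35 (1.79 to 4.90) and Aoah by 3.05 (1.60 to 4.50), so both differences kept their size. Their calls ended (limma adjusted p = 0.179 for both, against 0.0432), with limma's SE at 0.499 and 0.470 in place of 0.426 and 0.399. Both genes were picked on these same arrays for a large difference with little spread within groups, which favours this outcome. Array spread is therefore not excluded. That deletion raises these genes within HSCs may be put as a hypothesis. Cre, which WT mice lack, is also carried by Het mice. Tyrobp read 6.11 ± 0.566 and Aoah 3.40 ± 0.744 in Het cells, below every KO array. KO minus Het was 2.78 and 2.53, not past the threshold over all genes (limma adjusted p = 0.198 and 0.206). For these 2 genes the values argue against Cre alone, with the Het level of Aoah in the range of absent transcripts. The 3 cell types, cell types not listed and a changed mix of cells within a set are left open.

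Regroupings of the arrays were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In KO versus WT the real split called 7 genes and the highest of the others 1; 1 split reached 7. In Het versus WT the real split called 0 and the highest other 1, and in KO versus Het 0 and 0, so all 10 splits reached the real counts. For lists at the preset correlation the real split of KO and WT called 2 and the highest other 6, with 8 splits at 2 or more; for Het and WT 4 and 5, with 2 splits at 4 or more; and for KO and Het 0 and 5, with 10 splits at 0 or more. Splits that call several times the real count show that lists can pass at the preset correlation when arrays are not grouped by genotype. Structure among the arrays and a preset correlation that is too small were not told apart. For the allele series, 1 of 100 splits, the real one, reached 3 genes, and the highest other reached 2. That share is under 0.05 and argues against chance for that count, with no correction for the other counts regrouped here. The count was 0 without KO replicate 1, without KO replicate 2 and over all probe sets.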

How the results depend on the processing

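Terms for sex and for the interquartile range of the arrays, the fit without both WT 1 and KO 3, and the division of the WT arrays were chosen after seeing the data; the other settings were fixed before. Where no cause is named, the cause was not tested. Genes called in KO versus WT (7) numbered 4 among genes at or above the median level, where fewer were tested, 3 when quantile normalized again, 0 with the replicate block, 24 with array weights, 1 with only the 2 groups compared, 3 with sex as a term, 0 with the interquartile range as a term, 2 without both WT 1 and KO 3, 17 at an adjusted p under 0.10 and 344 at an unadjusted p under 0.01 and a fold of at least 1.5; leaving out 1 array gave 0 to 15. Over 21 fits Gm17745 was called in 14, Cysltr2, Sox18 and Tyrobp in 10, Ctla2a in 6 and F10 in 5, and Aoah in 7 of 20, all with unchanged direction. With all probe sets 7 were called as well, but 0 of these were among the 7 genes. Het versus WT (0) gave 189 at the unadjusted threshold and 6 with all probe sets; KO versus Het (0) gave 148 and, at an adjusted p under 0.10, 2. The allele series (3) gave 7 with the replicate block, 15 with array weights, 1 with sex, 0 with the interquartile range, 0 without both WT 1 and KO 3, 10 and 175 at the other thresholds, 0 with all probe sets, and 0 to 14 without 1 array.

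Lists called in KO versus WT (2) numbered 4 without a filter, 0 with an estimated correlation, 0 with fry and 2 to 5 without 1 array (4 without WT replicate 2, 5 without KO replicate 3). Those in Het versus WT (4) numbered 2 with sex, 1 without both WT 1 and KO 3, 0 with an estimated correlation, 0 with fry and 1 to 5 without 1 array (1 without WT replicate 1, 2 without WT replicate 3, Het replicate 1 or Het replicate 2). In KO versus Het (0) 1 list was called without a filter, with the replicate block, with array weights, with only the 2 groups compared and without both WT 1 and KO 3, and 0 to 1 without 1 array (1 without WT replicate 1, Het replicate 2 or KO replicate 3). HSC identity and aged genes in KO versus WT, and aged genes in Het versus WT, kept their calls in all 21 fits with the preset correlation, with medians of 0.31 to 0.77, 0.36 to 0.65 and 0.43 to 0.58. The correlation of the Het and KO changes (0.609) was 0.631 with sex, 0.585 with the interquartile range, 0.562 without both WT 1 and KO 3, 0.0878 with no WT array shared and 0.575 as Spearman's rho, and 0.451 (without Het replicate 3) to 0.741 (without WT replicate 3) without 1 array. Bcl11a kept its direction in KO versus WT in every setting run, at −0.223 (mean of all probe sets of the gene) to −0.78 (without KO replicate 3). In Het versus WT it turned to 0.0133 with sex as a term. Without 1 array it was −0.285 (without Het replicate 3) to −0.01 (without Het replicate 1).

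The other differences that changed sign had not passed the threshold. Ccnd1 in KO versus WT was −0.16 with the interquartile range as a term, −0.01 without both WT 1 and KO 3 and −0.075 (without WT replicate 1) to 0.465 (without WT replicate 2) without 1 array. Cdkn1c in KO versus WT was −0.00389 with sex and −0.0183 (without WT replicate 1) to 0.168 without 1 array; without Het replicate 2 it was −0.0367 in Het versus WT, with 0.358 as the highest value without 1 array, and 0.127 in KO versus Het, with −0.268 as the lowest. Slamf1 in KO versus Het was 0.0598 with array weights, 0.145 without both WT 1 and KO 3, and −0.61 (without KO replicate 1) to 0.145 (without KO replicate 3) without 1 array. Of the other values of named genes, 2413 stayed on their side of the threshold, 77 lost their call and 4 gained one. Most of the 2413 had no call to lose. The named genes called in KO versus WT, to which all 77 losses belong, kept their call in only 5 to 10 of 20 or 21 fits each.

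Replicate numbers did not pair the arrays: of 9 pairs with the same number 1 correlated above 0.1 (−0.185 to 0.229), and 2 of 9 arrays were closest to their own number. Dim signal limits the embryonic globins and each gene with a compared group in the range of absent transcripts. Among the genes given by the naming rule and Gm17745, 13 in KO versus WT, 6 in Het versus WT and 5 in KO versus Het had 1 such group, and 3, 1 and 2 had both (Il7r throughout, Cd79a and Cpa3 in the first and Flt3 in the last).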

Other observations

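Without the array labelled KO replicate 3, a fit planned in advance, 15 genes were called in KO versus WT, all higher in KO; these genes are named after their values were seen. Besides Tyrobp, Cysltr2, Sox18 and Gm17745 they were Arhgap29, B4galt6, C4b, Calml4, Chil5, Chrnb1, Dok5, Gimap4, Hid1, Neo1 and Sash1. In 12 of the 15 the omitted array still lay above all WT arrays. C4b, a complement gene, read 5.80 and 5.81 on KO replicates 1 and 2 and 4.90 on replicate 3, while Dok5, a docking protein of receptor kinases, read 5.28 and 5.47 on the first pair and 3.51 on replicate 3, against 3.21 to 3.58 in WT cells. In 8 of the 15 genes the WT mean lay in the range of absent transcripts, so their differences may start from background. These 8 were Arhgap29, C4b, Calml4, Dok5, Gimap4, Gm17745, Hid1 and Sox18. In all 15 genes the Het arrays lay below KO replicates 1 and 2, which a choice of genes high on these 2 arrays favours. Both of these KO arrays came from male mice, against 1 of 3 WT arrays, so sex and genotype are harder to separate in this fit.

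In the model with sex as a term, chosen after seeing the data, 4 of 16636 genes passed between the 5 male and 4 female arrays: Xist (3.94 in males and 11.3 in females), Eif2s3y (7.68 and 3.10), Kdm5d (6.22 and 2.60) and Myl10, a myosin light chain, which read 6.65 in males and 9.49 in females (−3.05 with genotype in the model, adjusted p = 0.0414). At an unadjusted p under 0.05, 800 genes differed, where chance gives 832. By genotype, Xist read 8.82 ± 4.28 in WT, 6.54 ± 4.15 in Het and 6.28 ± 4.38 in KO cells and Uty 3.17 ± 0.595, 4.10 ± 1.78 and 4.98 ± 2.12 (n = 3 each), as the uneven sexes of the groups give.

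The aged list shares Zfp36, Jun and Fosb with the stress list and Slamf1 and Mllt3 with the HSC list. Without the 3 stress genes its median was 0.46 in Het versus WT and 0.36 in KO versus WT (35 members), and without the 2 HSC genes 0.46 and 0.37 (36 members).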
